A study of Mus musculus with 8 samples.

How the data were processed

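RNA sequencing of brain microvessels from wild-type C57BL6 mice covered 4 sham and 4 tMCAO libraries, grouped by the treatment and title labels. Total RNA was depleted of ribosomal RNA before library preparation, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19, cutadapt, STAR, HTSeq and DESeq2 and the mouse build GRCm38 (mm10), with no roles, options, annotation release or other versions. Nothing in the labels says that the libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

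The deposited values are results of the authors' own comparison, and 0 columns hold values per library. The authors' deposited table gives a log2 fold change per gene, per the file headers, for 31616 of 48404 listed genes. A p-value, per the file headers, is deposited for 19294 of them, and the other 12322 genes with a fold change have none, for a reason not given in the sources used here. The deposited linear fold change (ratio) is 2 to the power of the log2 value. The deposited score of the authors, named z-score per the file headers, is a rescaled log2 fold change and not a test statistic. It equals the log2 fold change minus 0.0623, divided by 0.6427, the mean and SD over 18393 protein-coding genes, and was checked and not used further. The deposited p-value was read as Benjamini-Hochberg adjusted, because 3214 of its values are shared by several genes and in each case those genes differ in fold change, the step pattern that the adjustment leaves. If it is unadjusted, as its header reads, a further adjustment would call 4329 genes. The deposited log2 fold changes run from -2.67 to 6.64, and 8 values, 4 positive and 4 negative, of size 0.143 to 0.169, are each shared by 212 to 440 genes. These repeated values belong to genes without a deposited p-value. Values this small, each shared by so many genes, make it likely that the authors shrank the fold changes towards 0. The sources used here do not state it. If so, the printed folds, the implied standard errors and the tests built on them are affected.

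Because no values per library were analysed, the test fixed for that case before the data were examined was used: the authors' fold changes and adjusted p-values, at an adjusted p under 0.05. An unadjusted p was recovered by multiplying each adjusted p by its rank (the last rank of a shared value) and dividing by the number of tests, turned into a signed normal deviate, and divided into the log2 fold change to give an implied standard error. This assumes a two-sided test on a normal scale and unshrunken fold changes, so these errors are approximate; their median was 0.22, from 0.053 to 0.51. Sequencing depth per library is unknown here, so the precision of a value is given by its implied standard error. The largest ratio of last to first rank within a shared value was 1.03. Simulated data were drawn on a normal scale with these implied standard errors, so they cannot test the assumptions of a normal scale and unshrunken fold changes. They test the arithmetic of the recovery, and the shares called hold only under those assumptions. The simulation covered 19294 genes with 200 genes changed by a log2 value of 0.5, 1 or 2. With no other gene changed, 23.5%, 69.0% and 99.0% of them were called, and the median error of the implied standard error was 8.6%, 1.56% and 5.68%. After errors of that kind, larger in an earlier draw, were seen, a simulation closer to the share of genes called here, with 33.3% of the other genes also changed, was added; 52.0%, 90.0% and 100.0% were called.

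Before the data were examined, 36 gene lists of cell types, pathways and quality checks were fixed. None of the 13 mitochondrially encoded transcripts was matched, and that list was not analysed here. The sex check list was not tested as a group; none of its 4 tested genes passed 0.05. The other 34 lists were tested with limma 3.58.1 (cameraPR, R 4.3.3) on the signed deviates, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The correlation could not be estimated without values per library, so 0.05, 0.1 and 0.2 were tried. Tested on simulated data for 19294 genes drawn independently, the set test called 1 of 40 unchanged lists and 9 of 10 shifted lists. Without correlation between the simulated genes, this cannot show whether the preset correlation suits the lists. For each list the recovered p-values were also adjusted over the list alone.

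Genes named in the text follow a rule fixed before the data were examined: the 8 highest and 8 lowest log2 fold changes with a gene symbol and an adjusted p under 0.05; up to 4 members of each list with the smallest adjusted p; 10 barrier genes; and 3 noncoding or unnamed genes with the smallest adjusted p. The parts asking for a mean level of at least 50 and no overlap between groups could not be applied. Where fewer than 2 members of a list passed, the rule asked for the members with the highest level, and the smallest implied standard error stood in for it. The rule gave 140 genes, of which 5 are not reported here.

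Gene positions, transcript length, gene span and GC content came from GENCODE M21 on GRCm38, in which 47958 of the gene identifiers were found; 99.8% of tested protein-coding genes had length and GC. The trend in these was fitted by splines with 5 knots, leaving out the list under test where an explanation was tested. Gene families were formed from symbol stems with at least 10 tested protein-coding members, 198 in all, after the data were examined. The ribosomal protein, proteasome, initiation factor, glutamate receptor and potassium channel families were narrowed after their first tests to leave out other genes with a similar symbol. The mitochondrial ribosomal protein, sodium channel, calcium channel, protocadherin and GABA-A receptor families were also set by symbol patterns. That of the GABA-A receptor took alpha, beta, gamma and delta subunits alone. Bootstrap intervals used 10000 resamples at 95%. The genes of a list were resampled, so the intervals show the spread between genes and not that between libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. Alternatives covered the threshold, the reading of the p column, the genes counted as tests, the centring, the length and GC trend, and the statistic and correlation of the set test.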

Results

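Gene expression was measured by RNA sequencing in small blood vessels (microvessels) taken from the brains of wild-type C57BL6 mice. The 8 libraries formed 2 groups, 4 from sham-operated mice and 4 from mice with tMCAO, the transient middle cerebral artery occlusion model of stroke, in which a filament blocks and then frees an artery that feeds much of a cerebral hemisphere. How long the artery was blocked and how long after reopening the vessels were taken are not given in the sources used here. The values analysed were the authors' log2 fold change and p-value for each gene over the whole comparison, so levels per library, the spread between libraries, the sequencing depth and how many libraries followed a direction were not analysed here. The header of the fold change column names no numerator. Positive values were read as higher after tMCAO because acute injury genes such as Il6, Lif and Hmox1 carried large positive values, so the direction of those genes themselves is not independent evidence.

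The comparison asks which transcripts of cerebral microvessels differ after a stroke. Among genes with an adjusted p, those with the largest rises included secreted inflammatory mediators. Il11, a cytokine of the interleukin-6 family, was 99.5-fold higher after tMCAO in the authors' deposited table (log2 fold change 6.64, implied standard error 0.37, adjusted p = 1.18e-67). Ptx3, a secreted pattern recognition protein, was 61.5-fold higher and Il6 60.6-fold higher in the authors' deposited table. Csf3, the growth factor of neutrophils, rose by 5.59 on the log2 scale, Arg1 by 5.40, the acute phase gene Saa3 by 5.18, Lif by 5.14 and the chemokine gene Cxcl3 by 4.83 in the authors' deposited table. The smallest adjusted p in the authors' deposited table among the named genes belonged to Serpina3n, a protease inhibitor known from reactive astrocytes (log2 fold change 3.83, implied standard error 0.20, adjusted p = 9.97e-77).

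The largest falls were smaller than the largest rises and included genes of neurons and microglia. Gpr6, a receptor gene of striatal neurons, was 6.35-fold lower after tMCAO in the authors' deposited table (log2 fold change -2.67, implied standard error 0.39, adjusted p = 1.22e-09). Tac1, which encodes the substance P precursor, had a log2 fold change of -2.37 in the authors' deposited table. Siglech, a microglial surface receptor gene, had a log2 fold change of -2.46 in the authors' deposited table, beside Serpina9 at -2.59, Ms4a15 at -2.55, Slc10a4 at -2.50 and Slc35d3 at -2.40. Of 19294 genes with an adjusted p, 6332 (32.8%) passed 0.05, 2941 higher and 3391 lower after tMCAO. An absolute log2 fold change of at least 1 was reached by 923 of the higher and 953 of the lower genes. Tested against an absolute log2 fold change above 1 with the implied standard errors, 140 genes were higher and 13 lower. The deposited fold changes were probably shrunken towards 0, which would affect these counts and the folds printed here. In the GENCODE M21 annotation of GRCm38, Il11 lies on chromosome 7 from 4772373 to 4782859, Serpina3n on chromosome 12 from 104406729 to 104414329 and Gpr6 on chromosome 10 from 41069977 to 41072285.

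Of 34 lists tested, 16 were higher after tMCAO, 4 were lower and 14 were not called by camera, a test of whether a list's genes shift relative to all other tested genes. Directions are relative to the median tested gene, whose log2 fold change was -0.0008. The median of the best measured genes was close to it, at -0.01. Centred on ribosomal protein genes instead, every log2 fold change would lie 0.90 lower, and the medians of 9 of the 16 lists called higher would fall below 0, while those of the cytokine, reactive astrocyte, neutrophil, matrix protease, monocyte, coagulation and oxidative stress lists would stay above it.

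Cytokine and chemokine genes rose almost throughout. Of 24 tested members of the list, 21 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 fold change of 2.21 and a camera adjusted p of 1e-29. Il18, singled out after its value was seen, was the member that fell, with a log2 fold change of -0.57 in the authors' deposited table. Genes of reactive astrocytes rose in 15 of 15 tested members (15 adjusted over the list alone, median 1.95, camera adjusted p = 1.2e-19). In the authors' deposited table Lcn2, an iron-binding secreted protein, rose by 3.65 on the log2 scale, Timp1, an inhibitor of matrix proteases, by 3.89 and Cd44, a hyaluronan receptor, by 2.85. Several of these genes, Lcn2, Timp1 and Cd44 among them, are also made by other cell types.

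Markers of circulating myeloid cells were higher after tMCAO. Neutrophil markers rose in 7 of 10 tested genes (8 adjusted over the list alone, median 2.40, camera adjusted p = 3.9e-10). In the authors' deposited table Trem1 rose by 3.87 on the log2 scale, Il1r2 by 3.15, the chemokine receptor gene Cxcr2 by 3.14 and S100a8 by 2.92. Monocyte and macrophage markers rose in 9 of 14 (9 adjusted over the list alone, median 1.23, camera adjusted p = 1.1e-07), including Itgam at 1.91, Chil3 at 2.23 and Plac8 at 2.06 in the authors' deposited table. Lymphocyte markers were tested for 3 of 13 genes, of which Cd4 fell (1 adjusted over the list alone), with a log2 fold change of -1.24 in the authors' deposited table, and the list was not shifted (camera adjusted p = 0.3).

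Among the endothelial markers, 9 of 16 rose and none fell (9 and 0 adjusted over the list alone, median 0.63, camera adjusted p = 0.0024). In the authors' deposited table Emcn, which encodes endomucin, rose by 1.14 on the log2 scale, the VE-cadherin gene Cdh5 by 1.18, Egfl7 by 1.04 and Esam by 0.91. With a preset inter-gene correlation of 0.1 the endothelial shift did not pass (adjusted p = 0.054). Neuron, oligodendrocyte and microglia markers were lower in the same comparison, with medians of -1.07, -0.69 and -0.63. A change in the share of each cell type cannot be told apart here from a change of expression within it.

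Barrier genes were not called as a group in the junction, transporter, transcytosis or Wnt lists. These lists were set against all tested genes and not against the endothelial markers, whose median was 0.63. Tight and adherens junction genes rose in 3 of 18 tested members, Cdh5 and F11r among them, and fell in Cldn12 (3 and 1 adjusted over the list alone, median 0.41, camera adjusted p = 0.11). The junction list did pass when ranks (adjusted p = 0.039) or the log2 fold change (adjusted p = 0.041) replaced the signed deviate in the test, and was then called higher. Cldn5, the main claudin of brain endothelium, had a log2 fold change of 0.47 with an adjusted p of 0.2 in the authors' deposited table. Ocln had a log2 fold change of 0.03 (adjusted p = 0.94) and Tjp1 one of 0.25 (adjusted p = 0.49) in the authors' deposited table. Barrier transporter genes rose in 1 of 21 and fell in 2 (1 and 1 adjusted over the list alone, median 0.00, camera adjusted p = 0.81). The amino acid transporter subunit gene Slc3a2 rose by 0.49 on the log2 scale, while the thiamine transporter gene Slc19a3 had a log2 fold change of -0.83 and Slc7a5 one of -0.33 in the authors' deposited table. The glucose transporter gene Slc2a1 had a log2 fold change of 0.18 (adjusted p = 0.48) and the efflux pump gene Abcb1a one of -0.25 (adjusted p = 0.37) in the authors' deposited table. Centred on ribosomal protein genes, Ocln, Tjp1, Slc2a1 and Abcb1a would be called lower. Ribosomal protein genes themselves rose in 76 of 80 tested members, so that centring lowers every gene. Of the 15303 genes it called, 14972 were lower, so it cannot show whether these barrier genes fell. The median log2 fold change was -0.01 for the best measured genes and -0.0008 for all tested genes. Centred on the best measured genes, 134 of 135 named genes kept their result, and none of these barrier genes was called. The lower calls therefore depend on the choice of reference.

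Plvap and Mfsd2a, a pair of genes tied to transport through endothelial cells, changed in opposite directions. Plvap, the diaphragm protein of endothelial fenestrae and caveolae, was 3.46-fold higher in the authors' deposited table (log2 fold change 1.79, implied standard error 0.25, adjusted p = 1.01e-10). Mfsd2a, a lipid transporter that restrains transcytosis, was 1.58-fold lower in the authors' deposited table (log2 fold change -0.66, implied standard error 0.20, adjusted p = 0.006). The transferrin receptor gene Tfrc had a log2 fold change of -0.73 in the authors' deposited table. The list of transcytosis and caveolae genes rose in 4 of 16 members, Plvap among them and, singled out after their values were seen, Ehd2 and Cavin3, and fell in 2 (4 and 2 adjusted over the list alone, median 0.24, camera adjusted p = 0.089). Plvap lies on chromosome 8 from 71497765 to 71511752, Mfsd2a on chromosome 4 from 122946850 to 122961188 and Cldn5 on chromosome 16 from 18776847 to 18778262 in the same annotation. Wnt and barrier regulator genes rose in 3 of 20 members, Ppard, Sox18 and Foxf2, and none fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.17).

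**Figure D1:**
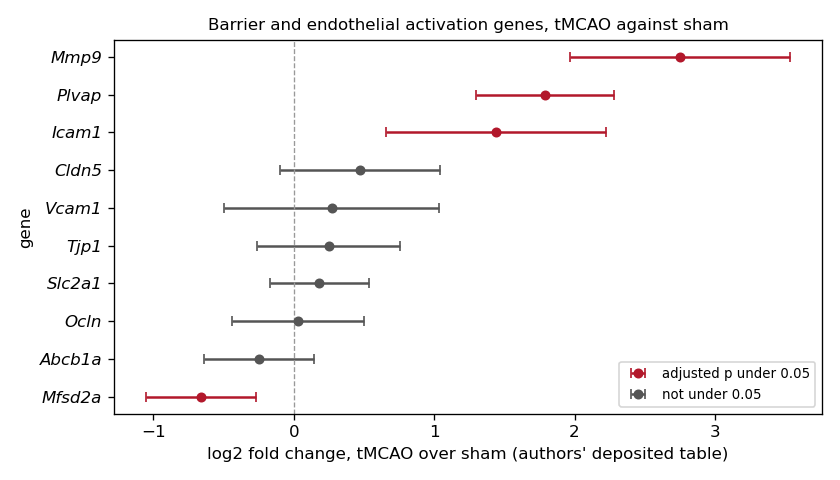
Log2 fold change, tMCAO over sham, from the authors' deposited table (x axis) for the 10 barrier and endothelial activation genes fixed before the data were examined (y axis). Points are the deposited values, bars are 95% normal intervals from the implied standard errors, and red marks an adjusted p under 0.05; Mmp9, Plvap and Icam1 lie to the right of 0 and Mfsd2a to the left, and on a scale centred on ribosomal protein genes every point lies 0.90 lower.

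Genes of leukocyte adhesion and endothelial activation rose in 7 of 13 tested members and fell in 2 (8 and 2 adjusted over the list alone, median 0.85, camera adjusted p = 0.00078). Ackr1, the chemokine receptor of venular endothelium, rose by 2.51 on the log2 scale and Itgb2, the shared chain of leukocyte integrins, by 1.36 in the authors' deposited table. Icam1, an adhesion receptor for leukocytes, was 2.71-fold higher in the authors' deposited table (adjusted p = 0.0022), whereas Vcam1 had a log2 fold change of 0.27 with an adjusted p of 0.63. The members that fell, singled out after their values were seen, were Cd47 at -0.54 and Itga4 at -0.40 in the authors' deposited table. With a preset inter-gene correlation of 0.2 the list did not pass (adjusted p = 0.092).

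Matrix protease and inhibitor genes rose in 14 of 19 tested members and fell in 1 (14 and 1 adjusted over the list alone, median 2.07, camera adjusted p = 3.1e-13). Adamts9 rose by 3.15 on the log2 scale, the urokinase receptor gene Plaur by 3.06 and the gelatinase gene Mmp9 by 2.75 in the authors' deposited table. Timp4, singled out after its value was seen, was the member that fell, with a log2 fold change of -0.64 in the authors' deposited table. Mmp9 is also abundant in neutrophils, whose markers were higher in the same samples (median 2.40). Basement membrane genes rose in 9 of 16 members and fell in 1 (10 and 1 adjusted over the list alone, median 0.84, camera adjusted p = 0.00049), with the collagen IV genes Col4a1 at 2.04 and Col4a2 at 1.84 in the authors' deposited table. Agrn, singled out after its value was seen, was the member that fell, with a log2 fold change of -0.29 in the authors' deposited table.

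Coagulation and fibrinolysis genes rose in 11 of 16 tested members and none fell (12 and 0 adjusted over the list alone, median 0.98, camera adjusted p = 3e-08). Procr, which encodes the endothelial protein C receptor, rose by 1.94 on the log2 scale and the urokinase gene Plau by 2.07 in the authors' deposited table. Angiogenesis genes rose in 13 of 20 and none fell (13 and 0 adjusted over the list alone, median 0.82, camera adjusted p = 2.6e-07). Apln, the ligand of the apelin receptor, rose by 3.03 on the log2 scale, Lrg1 by 2.65, Adm by 1.96 and the Notch ligand gene Dll4 by 1.15 in the authors' deposited table. Complement genes rose in 5 of 13 and none fell (9 and 0 adjusted over the list alone, median 0.81, camera adjusted p = 1.1e-05), with C3 at 3.13, C5ar1 at 1.82, C1ra at 1.46, C1s1 at 1.33 and, singled out after its value was seen, C3ar1 at 0.86 in the authors' deposited table. Interferon response genes rose in 10 of 18 and none fell (14 and 0 adjusted over the list alone, median 0.65, camera adjusted p = 0.00012), with Ifitm3 at 1.81 and Irf7 at 0.80 in the authors' deposited table. With a preset correlation of 0.2 the basement membrane (adjusted p = 0.094) and interferon (adjusted p = 0.089) shifts did not pass.

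The heat shock and oxidative stress lists were both called higher. Heat shock and unfolded protein response genes rose in 16 of 18 tested members and none fell (16 and 0 adjusted over the list alone, median 0.72, camera adjusted p = 1.6e-09). The transcription factor gene Xbp1 rose by 1.14 on the log2 scale (implied standard error 0.15, adjusted p = 1.43e-11) in the authors' deposited table. Hspa1b rose by 2.40 and Hspa1a by 1.99 in the authors' deposited table, though these near-identical genes can share reads. Oxidative stress and metal response genes rose in 11 of 18 and none fell (14 and 0 adjusted over the list alone, median 0.93, camera adjusted p = 2.1e-09), with the heme oxygenase gene Hmox1 14.0-fold higher and the metallothionein gene Mt2 7.61-fold higher in the authors' deposited table.

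Immediate early genes rose in 11 of 20 members and fell in 3 (11 and 4 adjusted over the list alone, median 0.65, camera adjusted p = 0.0029). Fosl1, an AP-1 subunit gene, rose by 4.81 on the log2 scale, Myc by 2.51 and Atf3 by 1.79, while Egr3 had a log2 fold change of -1.62 in the authors' deposited table. Nr4a1 at -1.05 and Nr4a3 at -1.02, singled out after their values were seen, were the other members that fell in the authors' deposited table. Hypoxia response genes rose in 5 of 20 and none fell (5 and 0 adjusted over the list alone, median 0.22, camera adjusted p = 0.015), among them the glycolytic genes Hk2, Ldha and Pgk1, 2.82-fold, 2.23-fold and 1.65-fold higher in the authors' deposited table. The others that rose were Adm and, singled out after its value was seen, Eno1 at 0.32 in the authors' deposited table. The hypoxia shift did not pass with a preset correlation of 0.05 (adjusted p = 0.068) or once a trend in gene length and GC content was removed (adjusted p = 0.19), and the shift of immediate early genes did not pass at 0.1 (adjusted p = 0.078). Cell cycle genes rose in 5 of 17 and none fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.055), with Ccnd1 at 1.26, the replication genes Mcm2 at 1.14 and Top2a at 1.09, Cdkn1a, an inhibitor of cell division, at 1.59 and, singled out after its value was seen, Mcm5 at 0.75 in the authors' deposited table. The cell cycle list passed with the log2 fold change as the statistic (adjusted p = 0.041). Cholesterol synthesis genes rose in 4 of 16, Idi1, Hmgcs1 and Mvd among them, and none fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.12).

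**Figure D2:**
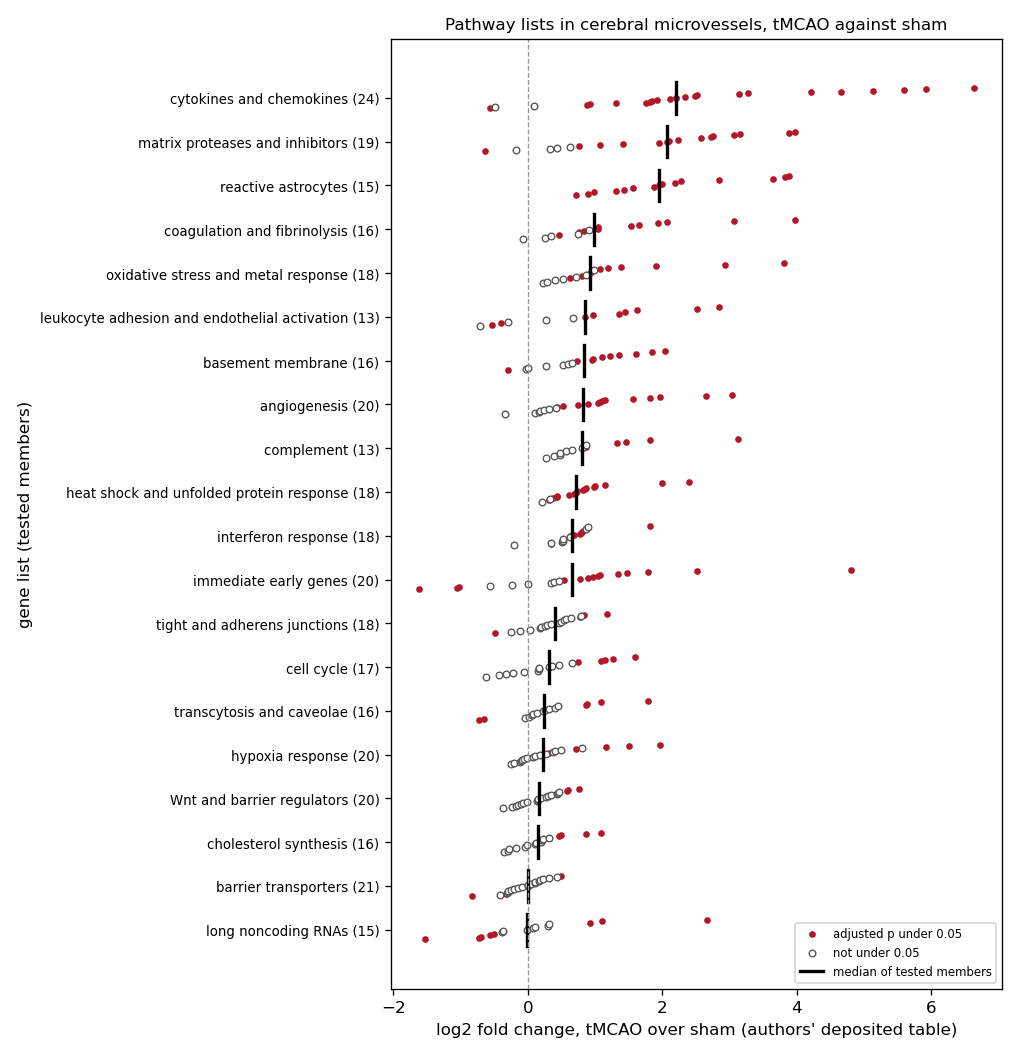
Log2 fold change, tMCAO over sham, from the authors' deposited table (x axis) of the tested members of each pathway list (y axis, number tested in brackets). Filled red points have an adjusted p under 0.05, open points do not, and black bars are medians, which run from -0.02 for long noncoding RNAs to 2.21 for cytokines and chemokines; centred on ribosomal protein genes, every value lies 0.90 lower, and the medians stay above 0 for the cytokine, matrix protease, reactive astrocyte, coagulation and oxidative stress lists and lie below 0 for all others shown.

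Neuron markers fell in 15 of 15 tested genes (15 adjusted over the list alone, median -1.07, camera adjusted p = 1.6e-09). The inhibitory neuron genes Slc32a1 and Gad1 had log2 fold changes of -1.74 and -1.36, the synaptic vesicle gene Syt1 one of -1.50 and the neurofilament gene Nefl one of -1.31 in the authors' deposited table. Oligodendrocyte precursor markers fell in 10 of 10 (10 adjusted over the list alone, median -1.13, camera adjusted p = 2.7e-08), including C1ql1 at -1.46 and Bcan at -1.08 in the authors' deposited table. Oligodendrocyte markers fell in 7 of 12 and none rose (10 and 0 adjusted over the list alone, median -0.69, camera adjusted p = 0.0013), with the myelin gene Mog at -1.37 in the authors' deposited table. With a preset correlation of 0.2 the oligodendrocyte shift did not pass (adjusted p = 0.094).

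Microglia markers fell in 7 of 12 tested genes and none rose (8 and 0 adjusted over the list alone, median -0.63, camera adjusted p = 1.5e-05). In the authors' deposited table Gpr34 had a log2 fold change of -2.23, the purinergic receptor genes P2ry12 and P2ry13 had -1.74 and -1.48, and Siglech had -2.46. Astrocyte markers fell in 3 of 12, Gpr37l1, Fgfr3 and Ntsr2, and none rose (3 and 0 adjusted over the list alone, median -0.16, camera adjusted p = 0.2), while 15 of 15 reactive astrocyte genes rose.

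Pericyte markers rose in 2 of 12 genes and fell in 2 (2 and 2 adjusted over the list alone, median 0.04, camera adjusted p = 0.54). The potassium channel genes Kcnj8 and Abcc9 rose by 0.83 and 0.45 on the log2 scale, and Art3 and Cspg4 had log2 fold changes of -0.61 and -0.42 in the authors' deposited table. Smooth muscle markers rose in 1 of 10, Des (0 adjusted over the list alone, camera adjusted p = 0.4), and fibroblast markers in 3 of 10, Col3a1, Dcn and Lum (3 adjusted over the list alone, median 0.65, camera adjusted p = 0.11). The fibroblast list passed with the log2 fold change as the statistic (adjusted p = 0.0095). Erythroid and platelet markers rose in 2 of 11, Itga2b and Pf4, platelet genes both (2 adjusted over the list alone, camera adjusted p = 0.2). The platelet gene Gp9, singled out after its value was seen, did not pass in the authors' deposited table (log2 fold change 0.09, adjusted p = 0.89). Choroid plexus and ependymal markers rose in 1 of 10, Foxj1 (1 adjusted over the list alone, camera adjusted p = 0.22).

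**Figure D3:**
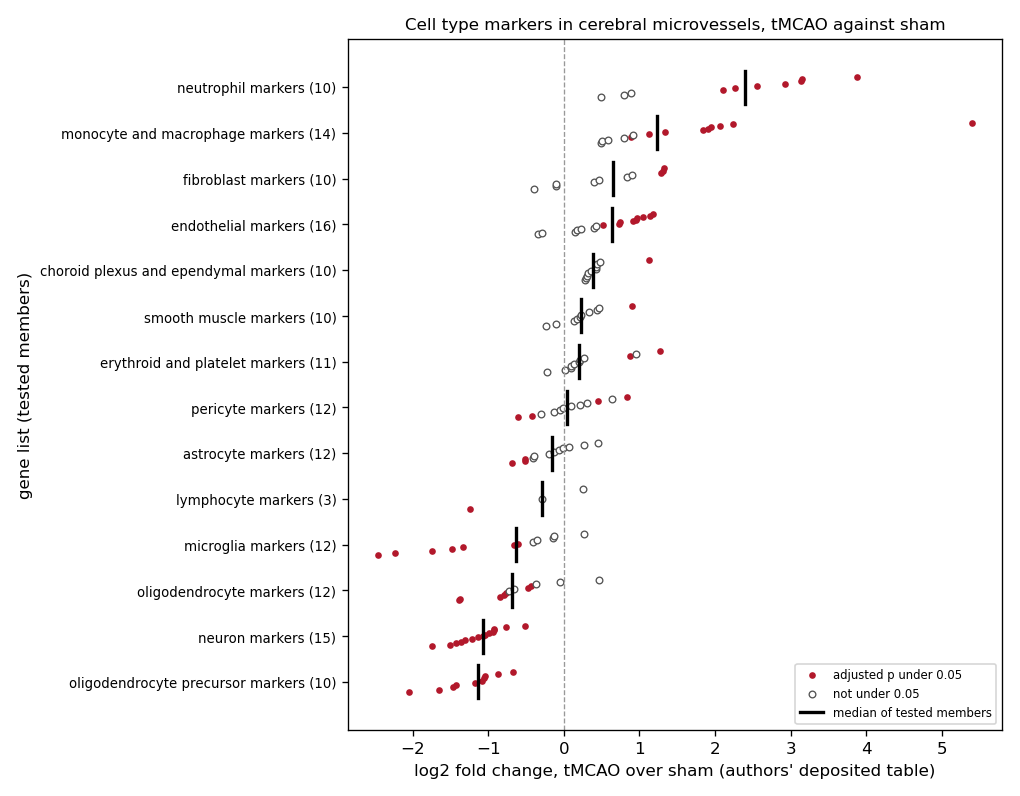
Log2 fold change, tMCAO over sham, from the authors' deposited table (x axis) of the tested members of each cell type list (y axis, number tested in brackets). Filled red points have an adjusted p under 0.05, open points do not, and black bars are medians, which run from -1.13 for oligodendrocyte precursor markers to 2.40 for neutrophil markers; centred on ribosomal protein genes, every value lies 0.90 lower, and the medians stay above 0 for neutrophil and monocyte markers and lie below 0 for all others shown.

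Long noncoding RNAs fixed beforehand rose in 3 of 15 and fell in 5 (4 and 5 adjusted over the list alone, median -0.02, camera adjusted p = 0.81). The imprinted transcript H19 rose by 2.66 on the log2 scale, Neat1 by 1.10 and Snhg1 by 0.93, while the interneuron-associated antisense transcript Dlx6os1 had a log2 fold change of -1.53 in the authors' deposited table. The others that fell, singled out after their values were seen, were Rian at -0.72, Meg3 at -0.70, Snhg11 at -0.56 and Miat at -0.50 in the authors' deposited table. The noncoding or unnamed genes with the smallest adjusted p were RP24-286J21.7, Sap30bpos and B430306N03Rik, with log2 fold changes of 1.76, 2.68 and 2.42 in the authors' deposited table. Whether reads were counted by strand is not given in the sources used here, so values of antisense genes may include reads of the overlapping gene. Among protein-coding genes with a fold change and no adjusted p, 140 had a log2 fold change of at least 1, 22 of them at least 2, and 27 had one of -1 or below. The largest was that of the transglutaminase gene Tgm1 at 6.18 in the authors' deposited table. Others were the matrix protease gene Mmp12 at 4.94 and the endothelial tip cell gene Esm1 at 3.35, in the authors' deposited table; all 3 were singled out after their values were seen and carry no test.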

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

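The alternatives of centring, p column, genes tested, length and GC, and those of the set test were chosen after seeing the data; the threshold of 0.01 and the test against a fold change were planned. No paired analysis was possible because the sham libraries are numbered 1 to 4 and the tMCAO libraries 5 to 8, with no shared number. Without values per library, other count tests, normalizations, quantile scaling, low-value filters, pseudocounts, variance models, sample weights, leaving out each library, estimated inter-gene correlation, fry and the structure of the samples were not run, and neither were other splits of the samples.

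Of 6332 genes, 4220 passed an adjusted p of 0.01 (1885 of 2941 higher ones), and 153 passed a test against an absolute log2 fold change above 1 (140 higher, 13 lower), fewer by construction. Reading the p column as unadjusted left 4329 genes, 1941 of them higher. Centring on ribosomal protein genes, whose median was 0.90, called 15303 genes, 331 higher and 14972 lower, 2.2% higher against 46.4%; it moves every gene by the same amount. With a correlation of 0.2, 10 lists in place of 16 were called higher. The other alternatives gave 5590 to 6320 genes. The 6320 came from centring on the best measured genes, whose median was -0.01. With the length and GC trend removed, which leaves protein-coding genes, the balance of calls reversed, with 3108 higher and 2653 lower (53.9% higher), against 2956 and 3156 (48.4%) for protein-coding genes alone; the cause was not tested further. The log2 fold change as the statistic added the junction, fibroblast and cell cycle lists to those called higher, and all log2 fold changes without a filter also the choroid plexus list, 20 in all. No list called higher was called lower under any setting of the set test tried. The set test was not run with the values centred on ribosomal protein genes.

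Of 135 named genes, 16 that rose turned negative when centred on ribosomal protein genes: Abcc9 -0.44, F11r -0.12, Foxf2 -0.30, Hmgcs1 -0.43, Hspe1 -0.07, Idi1 -0.03, Irf7 -0.09, Irf9 -0.21, Itga2b -0.01, Kcnj8 -0.07, Mvd -0.41, Pgk1 -0.18, Ppard -0.32, Slc3a2 -0.41, Sox18 -0.14 and Stat2 -0.55. Another 24 that rose kept their sign and lost their call, and 7 that were not called were called lower: Abcb1a, Ocln, Slc2a1, Tjp1, Mylk, Kdm5d and Uty. No call changed sign among the 129 of them with a value after the length and GC trend was removed, where 4 lost their call and Uty gained one. With the p column read as unadjusted, 9 of the 135 lost theirs, with no filter 2, and centred on the best measured genes 1.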

Other observations

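Chosen after the result was seen were the symbol families, the comparisons of astrocyte, oligodendrocyte, precursor and microglia markers with neuron markers and the test of equal falls among microglia markers; the lists of striatal and cortical neuron genes were also written after the data were examined, before their values were seen.

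Of 198 symbol families tested with camera, 14 were higher and 16 lower after tMCAO at the preset correlation of 0.01; 3 and 6 of these passed at a correlation of 0.1, and 10 and 12 with the length and GC trend removed. Ribosomal protein genes rose in 76 of 80 tested members and none fell (median log2 fold change 0.90, adjusted p = 2.5e-16, and 0.003 at a correlation of 0.1). Proteasome subunit genes (Psm) rose in 31 of 34 and none fell (median 0.64, adjusted p = 7.4e-11, and 0.003 at a correlation of 0.1). Translation initiation factor genes (Eif) rose in 26 of 44 and none fell (median 0.47, adjusted p = 1.3e-06), though at a correlation of 0.1 they did not pass (adjusted p = 0.085). Centred on ribosomal protein genes, the Psm and Eif medians would be negative. Mitochondrial ribosomal protein genes (Mrp) rose in 21 of 76 and fell in 1, Mrpl41, named after its value was seen (adjusted p = 0.00037), and did not pass once the length and GC trend was removed (adjusted p = 0.38).

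Ion channel and receptor families of neurons were lower. GABA-A receptor genes of the alpha, beta, gamma and delta subunits (Gabr) fell in 12 of 12 (median -1.41, camera adjusted p = 1.7e-08). Sodium channel genes (Scn) fell in 10 of 12 (median -1.39, adjusted p = 1e-06) and ionotropic glutamate receptor genes (Gri) in 16 of 17 (median -1.0, adjusted p = 3.9e-08). Potassium channel subunit genes (Kcn) fell in 54 of 78 and rose in 5 (median -0.84, adjusted p = 1e-10); those that rose in the authors' deposited table were Kcnj15, Kcnk5, Kcnq1, Kcne4 and Kcnj8, named after their values were seen. These 4 families passed with the length and GC trend removed and with a correlation of 0.1.

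Among 3 explanations tested for the fall of the neuron markers, a trend in gene length or GC is argued against, since the median log2 fold change was -0.97 (95% interval -1.36 to -0.85) after the trend was removed, from -1.07 before. All intervals in this comparison resample genes and leave out the spread between libraries. Less brain tissue of every kind, lost evenly and with expression unchanged, is argued against as the whole cause, since the astrocyte median lay above the neuron median by 0.90 (0.54 to 1.24) and the oligodendrocyte median by 0.37 (0.17 to 0.82). Oligodendrocyte precursor and microglia medians were not separated from the neuron median, with differences of -0.06 (-0.48 to 0.27) and 0.44 (-0.54 to 0.90), so a fall shared with these cells stays open. A change of expression in astrocytes stays open too. In the reactive astrocyte list 15 of 15 genes rose, though several are also made by other cell types. Whether striatal neurons were affected more than cortical neurons stays open: the striatal median minus the cortical median was -0.22 with an interval of -0.70 to 0.15, which reaches both sides of 0. Loss of neuronal RNA after tMCAO, or less neuronal tissue alone attached to the vessels, may each underlie the fall, and neither was tested.

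Microglia markers split: Gpr34, Siglech and P2ry12 fell strongly, while Trem2, Tmem119 and Fcrls, named after their values were seen, did not pass the threshold. Fewer microglia with unchanged expression would lower every marker alike, and the markers differed by more than their implied standard errors (Cochran Q = 129 on 11 degrees of freedom, past the 0.05 threshold). A trend in gene length or GC is argued against too, since the SD of their log2 fold changes was 0.91 after the trend was removed and 0.89 before. A change of expression within microglia, or macrophages that share some of the markers, may add to a fall in number and was not tested.

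The rise of ribosomal protein genes was tested against a trend in gene length or GC and against a shift of all short transcripts. After removal of the trend their median was 0.69 (0.63 to 0.79 over resampled genes), from 0.90 before, which argues against the trend as the whole cause. That interval leaves out the spread between libraries. Lists of other genes matched on length and GC, 10000 of them, had a median of 0.23, with 95% of them from 0.12 to 0.33, below the ribosomal median. The scaling of the libraries moves every gene by the same amount, so the gap between the ribosomal median and these matched lists argues against it as the whole cause. Reads shared with ribosomal protein pseudogenes and a rise in translation capacity after tMCAO may each contribute and were not tested.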
